A study of Homo sapiens with 2 samples.

How the data were processed

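Total RNA was extracted with Trizol from young (population doubling level 20) and senescent (level 52) WI-38 lung fibroblasts, per the labels' protocols. Complementary DNA was made and amplified with the NuGEN Ovation RNA-Seq System V2, which takes up RNA with and without a polyA tail, then sheared and sequenced on an Illumina platform, per the labels' protocols. TopHat2 2.0.6, Cufflinks 2.0.2 and Cuffdiff on hg19 are named per the submitters' processing notes, without their order or settings. The annotation and the strand of the reads are not stated.

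The deposited file is a single table of transcripts, annotated ones and ones assembled from the reads. The authors gave each transcript an FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) in the young and in the old library, per the file headers. The column for the old library was taken as the senescent sample, since the other column is named young and the series holds 2 samples. The authors' p-value and q-value per transcript are also deposited, and in the file a transcript is marked significant when its status is OK and its q-value is under 0.1. The authors' fold change, a ratio of old over young per the file headers, equals the ratio of the FPKM columns, with 1 added to both where one of them is 0. It was not used, nor was the authors' log2 column, which holds placeholders for infinite values. Transcript length in bases, biotype, class and hg19 coordinates were taken from the deposited file. The GRCh38 annotation at hand was not used, because its coordinates are of another build.

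A gene's value was the sum of the FPKM of the transcripts classed as its isoforms. Ratios were computed as log2 of senescent over young after adding a pseudocount of 1 FPKM, which understates the difference of low genes. Folds given as such are plain ratios of FPKM. A gene, isoform or locus counted as measured at 1 FPKM or more in at least 1 library and as higher or lower at 2-fold on the pseudocount scale. With 1 library per group no test across genes was made, and this rule of size took its place. Long noncoding RNA genes were those with a noncoding long-RNA biotype in the file and a longest transcript of at least 200 bases. Unnamed loci were assembled transcripts without a gene name. Samples were grouped by their labels, young and senescent, and the only comparison was senescent against young.

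The 29 gene lists were compared with random lists. For each list with at least 3 measured members, the median log2 ratio was placed as a percentile among 10000 random lists of equal size, matched on mean expression in 10 bins with seed 1, and lists under 2.5 or above 97.5 stand outside the random range. The lists, the rule of size, the rule for named genes and 12 alternative settings were fixed before the data were examined. They cover CDK inhibitors, p53 targets, G2 and mitosis, DNA replication, histones, homologous recombination and Fanconi genes, chromatin proteins, cytokines, secreted proteases and growth factors, extracellular matrix, lysosome, interferon response, unfolded-protein and amino-acid response, immediate early genes, cholesterol synthesis, TGF-beta response and contractile genes. They also cover ribosomal proteins, mitochondrially encoded genes, oxidative phosphorylation, telomere genes, housekeeping genes, well-known long noncoding RNAs, small-RNA hosts, RNA polymerase III products and markers of fibroblasts, epithelium, endothelium and blood cells.

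Named genes were 21 fixed genes, the 10 genes of highest and the 10 of lowest ratio at 5 FPKM or more (without long noncoding RNAs, pseudogenes and small RNAs), and the 8 long noncoding RNA genes at each end. From each list the 3 measured members of largest absolute ratio and up to 2 others of highest mean FPKM were taken. The rule also took 3 unnamed loci at each end and the 5 genes with the largest gap between a higher and a lower isoform. Genes named outside this rule are marked as such.

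Depth is not given in the file. In unnamed loci with a single transcript, FPKM values step by whole fragments over a length reduced by 200 bases, which gave effective depths of 16000000 fragments in the young and 14900000 in the senescent library. Within a tolerance of 0.05, 94.9% of 332 such values in the young library and 96.0% of 531 in the senescent library were whole, against 10% by chance. Only values of low fragment number were tried. At higher numbers a value can miss the tolerance. Before rounding, XLOC_023166 came to 209.726 fragments in the young library and XLOC_025918 to 172.722 in the senescent library. Over loci of all kinds with a single transcript the shares were 24.9% of 2098 and 31.0% of 2633, so fragments were not recovered for annotated genes, and no count test was run. At 1200 bases, 1 fragment is worth 0.0626 FPKM in the young and 0.0672 in the senescent library. Intervals of the fold of single loci are exact binomial (Clopper-Pearson) at 95% on the estimated fragments.

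The procedure was tested on simulated data for 16819 genes of the senescent against young comparison. At a true 3-fold difference 82 of 98 genes (83.7%) were called in the right direction, and at 6-fold 90 of 93 (96.8%). Of genes simulated without a difference, 255 of 16628 (1.53%) were called through counting noise, and 44 of 10303 (0.427%) at 5 FPKM or more. Of simulated lists of 30 genes without a difference, 19 of 400 (4.75%) fell outside the random range. These lists were themselves drawn at random, so a share near this size was fixed in advance and says nothing on genes that vary together. The shares cover counting noise at a depth near those read from unnamed loci. They cover no error in assigning reads to isoforms and no variation between cultures.

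Alternatives were pseudocounts of 0.1 and 5, a minimum of 5 FPKM, no minimum, scaling by the median ratio, the upper quartiles or a trimmed mean, OK transcripts alone, the isoform of highest mean FPKM as the gene's value, 4-fold for opposite isoforms, random lists in 5 bins and a q-value threshold of 0.01. Added later were a fragment-weighted gene value, all transcripts listed under a gene, and leaving out transcripts under 200 bases. Left out were Y-linked genes and others that tell a donor's sex. Intronic, run-on, opposite-strand and other partial classes stayed out of gene values. Transcripts under 200 bases, 10743 in number, hold 72.7% of the summed FPKM in the young and 79.0% in the senescent library, so summed FPKM was not used for scaling. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.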

Results

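Total RNA of WI-38 cells, an established line of human lung diploid fibroblasts, was sequenced from 1 young culture at population doubling level 20 and 1 senescent culture at level 52. Each group holds 1 library, so there are no replicates, no spread between cultures is known, and every difference is a difference between 2 libraries without a test. The file lists 201728 transcripts after Y-linked genes and others that tell a donor's sex were left out. Of these, 126714 were above 0 FPKM in the young library and 123526 in the senescent library. The effective depth read from the steps of the values was 16000000 fragments for the young library and 14900000 for the senescent library. Paired values are given with the young library first and the senescent library second, and log2 ratios are those of senescent over young after a pseudocount of 1 FPKM was added to both. Statements that a gene was or was not 2-fold higher or lower are on this scale, on which low genes differ less than by their plain ratio.

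The first question was which genes differ between proliferating fibroblasts and fibroblasts at the end of their replicative life span. CCND2, which encodes cyclin D2, had the highest ratio of the named genes at 1.56 against 137 FPKM, log2 ratio 5.75. WNT16, a secreted Wnt ligand, was higher in the senescent library at 1.24 against 36.7 FPKM, as was MMP3, a matrix metalloproteinase, at 0.114 against 23.8 FPKM. At the other end, FBLN1, which encodes the matrix protein fibulin-1, stood at 668 against 18.6 FPKM, log2 ratio -5.10. PCOLCE, an enhancer of procollagen processing, was at 568 against 21.4 FPKM, log2 ratio -4.66, and LMNB1, which encodes lamin B1 of the nuclear envelope, at 37.5 against 0.901 FPKM, log2 ratio -4.34.

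The other genes of highest ratio were ADAMTS19 at 2.05 against 48.9 FPKM, ANGPTL4 at 0.736 against 27.0 FPKM, the insulin-like growth factor binding protein gene IGFBP7 at 49.2 against 741 FPKM, KRTAP2-3 at 3.57 against 49.1 FPKM and MT2A, a metallothionein, at 77.8 against 805 FPKM. IGHA1 and CST1 were listed at 0 in the young library and at 14.4 and 13.2 FPKM in the senescent library. IGHA1 has close paralogs, so its assignment is uncertain. The lowest ratios also included the collagen gene COL14A1 at 27.9 against 0.403 FPKM, ABI3BP at 37.2 against 1.06 FPKM, the receptor gene TNFRSF19 at 124 against 5.94 FPKM and the histone genes HIST1H1E, HIST1H1D, HIST1H1A and HIST1H3I, with log2 ratios from -4.45 to -4.09.

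Of 18205 genes at 1 FPKM or more in at least 1 library, 1228 were at least 2-fold higher and 1564 at least 2-fold lower in the senescent library. Genes higher made up 44.0% of those past 2-fold. After scaling by the libraries' upper quartiles, which adds 0.154 to each log2 ratio before the pseudocount, the counts were 1589 and 1319 and the share 54.6%, so the balance of the 2 directions depends on the scaling. With the median ratio the counts were 1403 and 1417 and with the trimmed mean 1400 and 1420, which leaves the balance near even and does not turn it. The median log2 ratio was -0.09 over 15142 genes at 1 FPKM or more in both libraries. Pearson's r of the log2 FPKM values was 0.918 across genes, which are not independent replicates. Among protein-coding genes, 799 of 12306 were higher and 1059 lower.

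**Figure D1:**
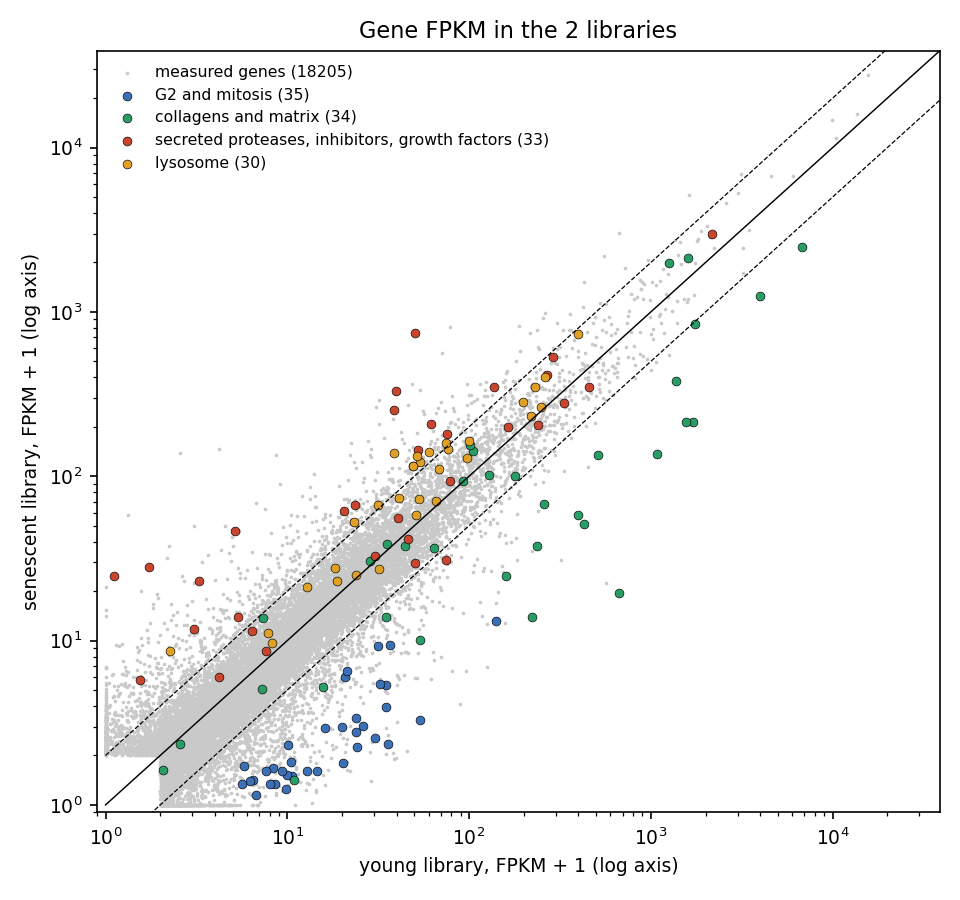
FPKM plus 1 of each of 18205 measured genes in the young library (x axis, log scale) and the senescent library (y axis, log scale), 1 point per gene, with 4 gene lists in colour, a solid line of equal values and dashed lines at 2-fold. All 35 G2 and mitosis genes lie under the lower dashed line, as do 19 of 34 collagen and matrix genes.

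Genes of cell division were lower in the senescent library without exception in the list of G2 and mitosis genes. All 35 measured members were at least 2-fold lower, with a median log2 ratio of -2.68. KIF20A, a mitotic kinesin, was at 52.7 against 2.30 FPKM, MKI67, the gene of the proliferation antigen Ki-67, at 34.7 against 1.33 FPKM, and TOP2A, a DNA topoisomerase, at 29.5 against 1.56 FPKM. ANLN, which encodes the cytokinesis protein anillin, was at 139.9 against 12.2 FPKM, and the cyclin genes CCNB1 and CCNA2 were at 35.6 against 8.35 FPKM and 9.14 against 1.32 FPKM.

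DNA replication and repair genes were lower as well. Of 39 DNA replication genes, 25 were at least 2-fold lower and 1 higher, with a median of -1.45. RRM2, a subunit of ribonucleotide reductase, was at 79.6 against 5.55 FPKM, the thymidylate synthase gene TYMS at 50.8 against 4.93 FPKM and the helicase gene MCM4 at 68.8 against 19.3 FPKM. The exception was CCNE1, which encodes cyclin E1 and was named after its values were seen, with a log2 ratio of 1.07. Of 16 homologous recombination and Fanconi genes, 13 were lower and 0 higher, with a median of -1.42. CLSPN, a checkpoint adaptor, was at 11.9 against 1.30 FPKM, the exonuclease gene EXO1 at 6.70 against 0.716 FPKM and the checkpoint kinase gene CHEK1 at 31.1 against 12.6 FPKM. The medians of these 3 lists lay under those of all 10000 random lists of equal size and matched expression.

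Chromatin genes showed the same direction, but histone genes were divided. Of 23 lamin, chromatin and high-mobility-group genes, 10 were at least 2-fold lower and 0 higher, with a median of -0.91 at percentile 0 of the random lists. HMGB2, a chromatin protein, was at 49.6 against 4.92 FPKM, the histone methyltransferase gene EZH2 at 10.4 against 1.52 FPKM and the histone variant gene H2AFZ at 332 against 106 FPKM. Of 46 replication-dependent histone genes, 19 were lower and 9 higher, with a median of -0.38 at percentile 0.59. The linker histone genes HIST1H1E, HIST1H1D and HIST1H1A were at 88.2 against 3.09, 44.7 against 1.14 and 38.7 against 0.917 FPKM. The core histone gene HIST1H2BK was at 33.2 against 169.8 FPKM, log2 ratio 2.32. The histone median was -1.29 when 5 FPKM were required.

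CDK inhibitors went both ways. CDKN1A, which encodes p21, was 2.82-fold higher at 306 against 862 FPKM. CDKN2A, the gene of p16 and p14ARF, was at 27.3 against 30.4 FPKM as a sum over isoforms, log2 ratio 0.15. This sum does not tell p16 from p14ARF, and isoforms were not assigned to either. The neighbouring gene CDKN2B, the gene of p15, was at 7.87 against 15.2 FPKM, log2 ratio 0.87. CDKN3, CDKN2C and CDKN1B were at 12.2 against 0.349, 3.32 against 0.210 and 21.8 against 8.75 FPKM, so that of 8 measured inhibitors 1 was at least 2-fold higher and 3 were lower. The list's median of -0.39 lay at percentile 11.1.

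For CDKN2A the sum over isoforms hid different isoforms. The 1218-base isoform CDKN2A-001 was at 0.959 against 7.08 FPKM and the 493-base isoform CDKN2A-011 at 14.2 against 19.6 FPKM, while the 1151-base isoform CDKN2A-201 was at 5.30 FPKM in the young library and listed at 0 in the senescent library. The authors' deposited table calls 1 CDKN2A isoform, as higher, with a q-value of 0.0614. For CDKN1A, too, 1 isoform is called higher in the authors' deposited table, with a q-value of 0.0786.

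Most p53 target genes differed little. Of 25 measured, 2 were at least 2-fold higher, CDKN1A and the kinase gene PLK3 at 5.97 against 13.9 FPKM, and 0 were lower. RRM2B, a p53-inducible subunit of ribonucleotide reductase, was at 14.7 against 29.9 FPKM, the p53 ubiquitin ligase gene MDM2 at 229.9 against 236 FPKM and CCNG1 at 134 against 122 FPKM. The median of 0.17 was at percentile 92.3, and with the highest isoform as the gene's value it was 0.44 at percentile 99.8.

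Secreted factors of senescent fibroblasts were higher as a group for proteases, inhibitors and growth factors and lower as a group for cytokines and chemokines, with exceptions in both. Of 33 measured genes of secreted proteases, inhibitors and growth factors, 17 were at least 2-fold higher and 1 lower, with a median of 1.23 at percentile 100. Besides MMP3, IGFBP7 and ANGPTL4, the collagenase gene MMP1 was at 51.6 against 143 FPKM. TIMP1, a metalloproteinase inhibitor, and PLAT, the tissue plasminogen activator, were abundant in both libraries at 2182 against 2981 and 289 against 533 FPKM.

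Of 16 measured cytokine and chemokine genes, 3 were higher and 7 lower, with a median of -0.75 at percentile 0.06. CCL2, a monocyte chemokine, was at 21.3 against 159 FPKM and TNFRSF11B, the decoy receptor osteoprotegerin, at 259.5 against 991 FPKM. The chemokine gene CXCL12 was at 15.7 against 0.626 FPKM, IL32 at 15.3 against 1.42 FPKM and the adhesion molecule gene ICAM1 at 28.3 against 5.78 FPKM. IL6, a cytokine of the senescent secretory state, was low in both libraries at 5.39 against 2.89 FPKM. The cytokine median was -1.71 over the 9 genes that reach 5 FPKM.

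Extracellular matrix genes were lower as a group. Of 34 measured collagen and matrix genes, 19 were at least 2-fold lower and 0 higher, with a median of -1.39 at percentile 0. POSTN, which encodes periostin, was at 220.5 against 13.0 FPKM, COL6A2 at 429 against 49.9 FPKM, COL1A1 at 3994 against 1242 FPKM and the fibronectin gene FN1 at 6809.7 against 2490.1 FPKM, from transcripts of status FAIL. Of 12 fibroblast markers 4 were lower and 0 higher, among them COL3A1 at 397 against 57.4 FPKM, FAP at 131 against 25.5 FPKM and DCN, the gene of decorin, at 512 against 133 FPKM, while VIM, the gene of vimentin, was at 3477 against 3131 FPKM. The fibroblast list's median of -0.35 sat at percentile 2.5, the edge of the random range, and held its side in 6 of 13 alternatives.

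TGF-beta responsive genes leaned higher in the senescent library and contractile genes differed little. Of 19 TGF-beta responsive genes 8 were at least 2-fold higher and 2 lower, with a median of 0.57 at percentile 100. The ligand gene TGFB2 was at 9.31 against 49.3 FPKM, the pseudoreceptor gene BAMBI at 1.51 against 9.35 FPKM and ID1 at 1.88 against 9.89 FPKM, whereas TGFBI was at 543 against 298 FPKM and CTGF at 198 against 221 FPKM. Of 14 contractile and myofibroblast genes 0 were higher and 2 lower, DES at 2.08 against 0.0604 FPKM and ACTG2 at 999.6 against 444 FPKM. Their median was 0.16 and their mean -0.02, at percentile 72.8, with TPM2 at 1120.2 against 1552 FPKM and CALD1 at 809 against 1197 FPKM. With the highest isoform as the gene's value the TGF-beta median was 0.33 at percentile 96.9.

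Lysosome genes were higher as a group. GLB1, the gene of the beta-galactosidase used to stain senescent cells, was at 99.5 against 163 FPKM, log2 ratio 0.71. Of 30 lysosome genes 9 were at least 2-fold higher and 0 lower, with a median of 0.65 at percentile 100. FUCA1, a fucosidase, was at 1.25 against 7.66 FPKM, the proton pump subunit gene ATP6AP1 at 37.7 against 138 FPKM and CD63 at 395 against 735 FPKM.

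Genes of amino acid supply and protein folding leaned lower in the senescent library. Of 20 unfolded-protein and amino-acid-response genes, 5 were lower and 1 higher, with a median of -0.56 at percentile 0.03. PHGDH, the first enzyme of serine synthesis, was at 34.5 against 3.78 FPKM and the asparagine synthetase gene ASNS at 21.1 against 4.24 FPKM. The cystine transporter gene SLC7A11 was the exception at 10.2 against 45.7 FPKM. The chaperone genes HSP90B1 and HSPA5 were at 470.0 against 319.6 and 277 against 188 FPKM. Of 23 cholesterol synthesis genes 2 were higher, SC5DL at 12.4 against 28.0 FPKM and SC4MOL at 20.8 against 44.8 FPKM, and 1 lower, STARD4 at 11.3 against 4.40 FPKM, with a median of 0.22 at percentile 93.4 (98.7 with the highest isoform).

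Of 26 interferon-response genes 4 were higher and 2 lower, with a median of 0.23 at percentile 99.2. IFI6 was at 3.76 against 33.3 FPKM, while ISG20 and the proteasome subunit gene PSMB9 were at 1.54 against 0.0403 and 7.31 against 2.73 FPKM. With only transcripts of status OK the interferon median was -0.08 at percentile 65.5, so this list's direction depends on that choice. Of 21 immediate early genes 3 were higher and 2 lower, with a median of -0.15 at percentile 35.3. The transcription factor gene EGR1 was at 27.6 against 3.91 FPKM, and the phosphatase genes DUSP6 and DUSP1 were at 8.30 against 37.3 and 15.1 against 36.4 FPKM.

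Ribosomal protein genes were lower by a small and shared amount. All but 2 of 70 stayed within 2-fold, and the median of -0.51 lay under all random lists. RPL3 at 1068 against 498 FPKM and RPL10A at 820.0 against 395 FPKM were the 2 past 2-fold, and RPLP2 was at 1214 against 1289 FPKM. None of 30 nuclear oxidative phosphorylation genes differed 2-fold, with a median of 0.22 at percentile 86.9 and ATP5B at 493 against 625 FPKM. None of 12 telomere genes differed 2-fold on the pseudocount scale. Their median was -0.04 and their mean 0.04, a sign that turns with the setting, with POT1 at 4.85 against 2.20 FPKM (a plain ratio of 2.21-fold) and NOP10 at 32.5 against 58.1 FPKM. None of 14 housekeeping genes differed 2-fold on that scale, with a median of 0.09 and a mean of -0.01 at percentile 61.7, ACTB at 10442 against 11369 FPKM, GAPDH at 2105 against 2847 FPKM and GUSB at 14.6 against 7.25 FPKM. No gene of the mitochondrial chromosome could be compared, since the only measured member of that list, MT-ATP8 at 4.01 against 5.79 FPKM, is placed in the file on chromosome 2 as a pseudogene.

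Few markers of other cell types were measured, and the epithelial and blood lists lay inside the random range. Of 4 measured epithelial markers 1 was higher, KRT18 at 2.84 against 6.75 FPKM, and 1 lower, KRT19 at 11.5 against 1.37 FPKM, with a median of -0.39 at percentile 22.2. Of 2 measured endothelial markers, the receptor gene TEK was at 18.8 against 8.16 FPKM and ROBO4 at 2.15 against 1.22 FPKM. The 3 measured blood cell markers were CD163 at 53.9 against 40.3 FPKM, CD74 at 2.36 against 0.752 FPKM and LYZ at 0.661 against 1.06 FPKM, with a median of -0.41 at percentile 24.6.

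**Figure D2:**
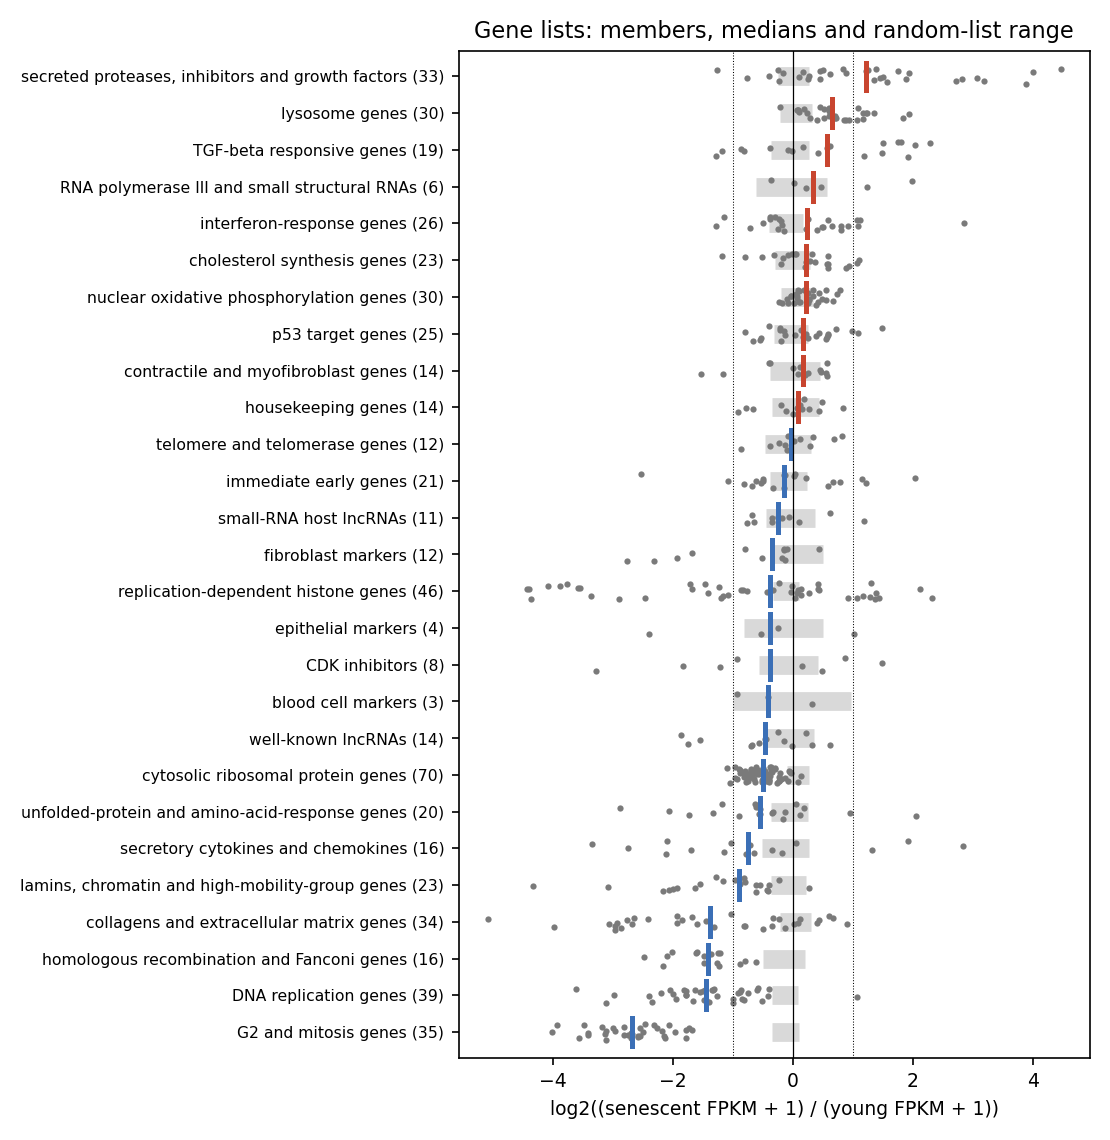
Log2 ratio of senescent over young after 1 FPKM was added to both (x axis) for each measured member (points) of the lists with at least 3 measured members, whose number stands in parentheses, with each list's median (coloured bar), the central 95% range of random lists (grey band) and dotted lines at 2-fold. The G2 and mitosis list has the lowest median at -2.68 and the list of secreted proteases, inhibitors and growth factors the highest at 1.23.

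The second question, named in the study's title, concerned long noncoding RNAs. Of 1492 measured genes of this kind, 79 were at least 2-fold higher and 106 lower in the senescent library. After scaling by the upper quartiles the counts were 103 and 94, which turns the balance, while they were 92 and 98 with the median ratio and 91 and 98 with the trimmed mean, which do not. The highest ratio was that of CTD-2021J15.2, a long intergenic RNA on chromosome 3 from 98699902 to 98701940 in hg19, at 1.17 against 30.9 FPKM, log2 ratio 3.88. RP11-656G9.3 was at 0.567 against 19.1 FPKM, RP11-46C20.1 at 0.566 against 9.43 FPKM and GS1-600G8.5 at 0.296 against 5.56 FPKM. The lowest ratio was that of RP11-394O4.2 on chromosome 5 from 148786252 to 148805957, at 11.9 against 0.353 FPKM, log2 ratio -3.25. RP11-458B24.2 was also lower, with a log2 ratio of -2.17.

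Several others lie over protein-coding genes that differed in the same direction. RP11-346A9.1 at 0.145 against 8.35 FPKM overlaps ADAMTS19, and RP4-541C22.4 at 10.3 against 56.6 FPKM overlaps CD59 at 102 against 279 FPKM. Among those lower, RP11-732A19.5 at 10.7 against 0.373 FPKM overlaps DCHS1 at 20.3 against 0.632 FPKM, RP11-25K19.1 at 6.01 against 0.281 FPKM overlaps TOX at 39.1 against 2.20 FPKM, and CTC-348L14.1 at 53.4 against 12.3 FPKM overlaps VCAN, the gene of versican, at 259 against 66.6 FPKM. RP11-301H24.4 and RP11-27M24.1 had log2 ratios of -2.39 and -2.22, and their partners SMAD1 and EMP2 of -2.33 and -1.17. In all, 8 of the 16 named long noncoding RNA genes overlap a measured protein-coding gene, and all 8 partners differed at least 2-fold in the same direction. The strand of the reads is not stated, so reads of one overlapping gene can be counted to the other.

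Across all 837 long noncoding RNA genes that overlap a measured protein-coding gene, Spearman's rho of the 2 log2 ratios was 0.496 and Pearson's r 0.546, across genes that are not independent replicates. Of the 118 that differed at least 2-fold, 99 had a partner of the same sign and 58 a partner at least 2-fold in the same direction. This comparison and the partner genes named were chosen after the values were seen. By the file's biotypes, 25 of 350 lincRNA genes were higher and 16 lower, against 31 higher and 58 lower of 592 antisense genes and 21 higher and 27 lower of 472 processed-transcript genes. BX571672.2 and BX004987.5, both higher at 0.191 against 8.30 and 0.239 against 8.55 FPKM, lie on the same stretch of chromosome 1, and whether they share reads was not tested.

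Well-known long noncoding RNAs gave gene totals that mostly stayed within 2-fold. Of 14 measured, 3 were lower and 0 higher, with a median of -0.46 at percentile 2.84. Those lower were MIAT at 2.39 against 0.159 FPKM, DLEU2 at 3.51 against 0.233 FPKM and MIR155HG, at 2.36 FPKM in the young library and listed at 0 in the senescent library. MEG3 was at 169 against 210.1 FPKM, TUG1 at 64.8 against 47.4 FPKM, PVT1 at 19.4 against 22.6 FPKM and the imprinted H19 at 1.04 against 0.384 FPKM. The authors' deposited table calls 1 MIAT isoform lower with a q-value of 0.0432 and 1 MEG3 isoform higher with a q-value of 0.00814.

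MALAT1 and NEAT1, abundant nuclear RNAs, had isoforms that differed far more than their totals. MALAT1 was at 1245 against 1233 FPKM as a sum, but its 8708-base isoform was at 6.82 against 267 FPKM and its 1031-base isoform at 1238 against 965 FPKM. With isoforms weighted by length, in proportion to fragments, the log2 ratio of MALAT1 was 1.31 in place of -0.01. NEAT1 was at 18.4 against 28.8 FPKM, log2 ratio 0.62 as a sum and 0.63 with that weighting, with a 22524-base isoform at 13.9 against 0.00317 FPKM and a 22743-base isoform at 4.41 against 28.8 FPKM. The authors' deposited table calls the 8708-base MALAT1 isoform and the longer NEAT1 isoform higher and the shorter NEAT1 isoform lower. Isoforms of one gene share reads, so the split between them is less certain than the total of fragments.

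Of 11 measured small-RNA host genes 1 was higher, SNHG9 at 1.05 against 3.66 FPKM, and 0 lower, with GAS5 at 194 against 121 FPKM and a median of -0.25 at percentile 16.1. Of 6 measured RNA polymerase III and small structural RNAs, RNU6ATAC at 0.206 against 3.77 FPKM and RPPH1, the RNA of ribonuclease P, at 34.7 against 83.4 FPKM were higher and 0 were lower. The nuclear 7SK RNA gene RN7SK was at 99.8 against 117 FPKM, and this list's median was 0.34 at percentile 90.3.

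**Figure D3:**
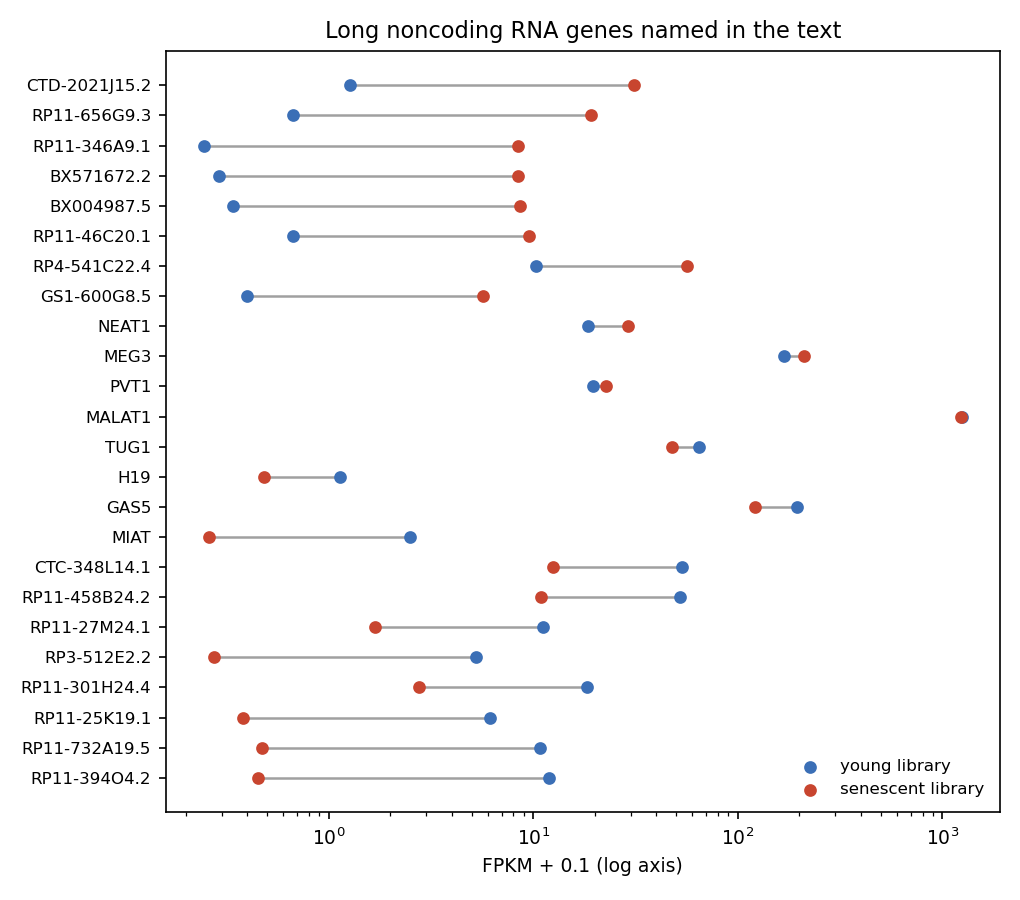
FPKM plus 0.1 (x axis, log scale) of 16 long noncoding RNA genes taken by their ratio and 8 well-known ones (y axis) in the young (blue) and the senescent library (red), with a line joining the pair of values of each gene. CTD-2021J15.2 stands at 1.17 against 30.9 FPKM and RP11-394O4.2 at 11.9 against 0.353 FPKM.

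The third comparison concerned loci that carry no gene name in the file. Of 7867 measured unnamed loci, 1425 were at least 2-fold higher and 2346 lower, and over loci of 200 bases or longer the counts were 1288 and 2237 of 7529. The 3 loci of highest and the 3 of lowest ratio by the fixed rule are 42 to 48 bases long, shorter than the sheared fragments, and each is listed at 0 in one library.

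Identifiers of 3 further loci were recalled from the study and not checked against its paper. If the study picked them on these same libraries, their direction here is not independent evidence. XLOC_023166, on chromosome 14 from 61105935 to 61107134, was at 13.1 against 0.805 FPKM. This was 16.3-fold lower in the senescent library (95% exact interval 9.13 to 32.02, from 210 and 12 fragments). XLOC_025918, on chromosome 15 from 70907887 to 70908906, was at 1.37 against 14.2 FPKM, 10.3-fold higher (6.34 to 17.8, from 18 and 173 fragments). XLOC_025931, on the same chromosome from 70927589 to 70929653, was at 3.31 against 27.8 FPKM, 8.37-fold higher (6.78 to 10.4, from 99 and 771 fragments). Fragments are estimated from the FPKM steps, and the intervals cover counting error only. In the authors' deposited table these 3 loci have q-values of 0.00017, 0.00286 and 0.000535.

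Both of the chromosome 15 loci lie in a long stretch of unnamed loci beside UACA, a gene on the minus strand from 70946893 to 71055932 that was at 131 against 346 FPKM. Drawn around UACA were the 93 measured unnamed loci that share their position with no other transcript. All 93 were at least 2-fold higher in the senescent library. UACA and its surroundings were examined after the values were seen.

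**Figure D4:**
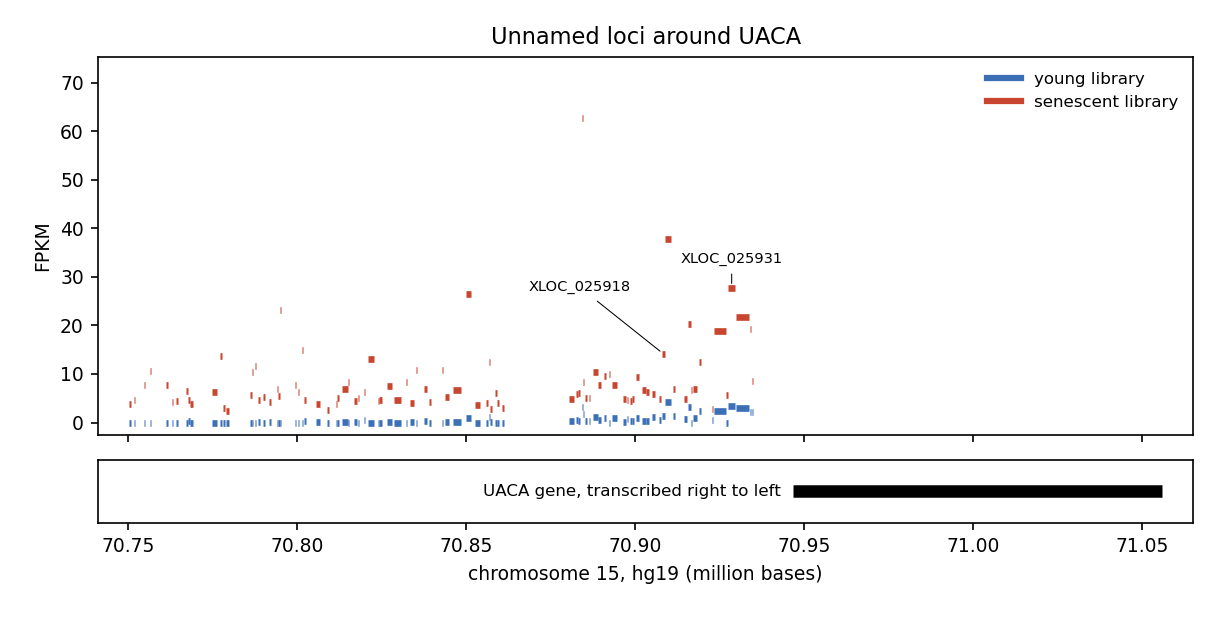
Unnamed loci around UACA on chromosome 15 by hg19 position (x axis) and FPKM (y axis, linear) in the young (blue) and the senescent library (red), each bar spanning its locus, with the gene drawn on a track of its own. All 93 loci, each the only transcript at its position, are at least 2-fold higher in the senescent library.

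The fourth comparison was made by isoform. Of 48643 measured isoforms, 5646 were at least 2-fold higher and 6385 lower. This balance turned under all 3 scalings tried, to 6191 and 6002 with the median ratio, 6186 and 6008 with the trimmed mean and 6694 and 5711 with the upper quartiles. Of 8967 genes with at least 2 measured isoforms, 1244 had one isoform 2-fold higher and another 2-fold lower, and in 1134 of these the gene's own ratio stayed under 2-fold. MGST3, a microsomal glutathione transferase gene, had a 680-base isoform at 114 against 0.0141 FPKM and a 678-base isoform at 0.236 against 163 FPKM. ANAPC11, a subunit of the anaphase-promoting complex, had an 870-base isoform at 88.9 against 0.0113 FPKM and an 862-base isoform at 0.0365 against 87.5 FPKM. CLIC4 had a pair of 2723-base isoforms at 36.9 against 0.0746 and 0.0165 against 38.4 FPKM. FN1 had a 7762-base isoform listed at 0 in the young library and at 99.6 FPKM in the senescent library beside a 7759-base isoform at 596 against 35.8 FPKM, and NFIX had a 1727-base isoform at 0.0103 against 13.4 FPKM beside a 1348-base isoform at 62.2 against 5.86 FPKM. All measured isoforms of MGST3, CLIC4 and FN1 carry the status FAIL in the file, so these genes have no value when only status OK is taken, where 1197 genes had opposite isoforms. Isoforms this alike share reads, so a switch between them is less certain than their gene's total.

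The authors' deposited table marks 3400 transcripts at a q-value under 0.1, 1424 of them higher and 1976 lower in the senescent library. Of the transcripts marked in the authors' deposited table, 55 belong to long noncoding RNA genes, 26 higher and 29 lower, and 232 are unnamed transcripts outside genes, 117 higher and 115 lower. WNT16 had 2 isoforms called higher in the authors' deposited table, ANLN 4 called lower and LMNB1 3 called lower. The file does not say how a spread was estimated from 1 library per group.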

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

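The tests of the side of UACA on which loci lie, of counting noise at the 3 loci recalled from the study, of a single scaling factor, and of shuffled loci far from measured genes were chosen only after the result was seen.

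Signal appeared in transcript classes that enter no gene value. Among transcripts within introns, 578 were at least 2-fold higher in the senescent library and 4013 lower. The counts were 323 higher and 843 lower for transcripts running past gene ends, 75 and 83 on the opposite strand of exons, 51 and 95 that overlap exons, and 26 and 35 of possible precursor RNA, so in each class more were lower than higher in the values as deposited.

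Intronic transcripts were lower in the senescent library: of 17329 at 200 bases or longer, 4013 were at least 2-fold lower, with a median log2 ratio of -0.56. A single scaling factor between the libraries is argued against, since the intronic median minus the isoform median was -0.49, and so is lower expression of the host genes, since the median was -0.51 over 5132 intronic transcripts of hosts whose own ratio lay within 0.25 of 0. Genomic DNA in the young library remains open. The excess of young over senescent FPKM hardly grew with host expression (Spearman's rho 0.0768 across hosts, which are not independent replicates). Only intronic transcripts of 1 FPKM or more in at least 1 library were taken. This drops weak signal of low hosts and can flatten the relation, so the rho does not decide the question. Over 687 unnamed loci of 200 bases or longer, more than 100 kb from any measured gene, the median was -0.75. All far loci given here share their position with no other transcript. Genes that were not measured may lie nearer to these loci. Against DNA as the whole source, intronic ratios followed those of their hosts (rho 0.517). With 1 locus per gene, that of highest FPKM, 174 far loci of any length had a median of 0.01. Both the lengths allowed and the choice of locus differ from the 687, so these medians cannot be set against each other. Less unspliced RNA in senescent cells may also account for the lower intronic transcripts and was not tested.

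The loci beside UACA make the second pattern. At the loci recalled from the study, all 3 exact intervals lay beyond 2-fold. If the study picked these loci for their difference in the same libraries, such intervals follow from the choice. No conclusion on counting noise is therefore drawn from them. RNA running past the 3' end of the neighbouring gene may contribute. Of the measured unnamed loci within 150 kb outside UACA, 70 share their position with no other transcript. All 70 (100%) lay on the 3' side of UACA, each at least 2-fold higher. That side holds 150000 bases free of annotated genes against 59444 on the other, so the counts are not on equal ground. The median log2 ratio of the 70 loci was 2.48, and 2.32 within 50 kb, against 1.396 for UACA itself. XLOC_025928 went the other way, at 1.25. Running-on from an equal share of UACA's RNA in both libraries would carry UACA's own ratio. The values argue against such running-on as the whole source of the 70 loci. Whether the share differs between the libraries was not tested. The median FPKM within 50 kb, from 50 to 100 kb and from 100 to 150 kb was 0.837, 0.340 and 0 in the young library and 6.84, 6.17 and 5.23 in the senescent library, over loci kept because they reach 1 FPKM, which mutes a decline, so separate transcripts of this region in senescent cells remain open.

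Unnamed loci elsewhere shared direction with nearby genes, again over loci that share their position with no other transcript. Over 1027 loci within 10 kb of the 3' side of a measured gene, 1 per gene, Spearman's rho of the log2 ratios was 0.46. Loci are not independent replicates, and the highest rho over 1000 shuffles was 0.103. RNA running past gene ends may account for part of this relation. On the 5' side rho was 0.284 over 490 loci. Over 174 loci more than 100 kb from any measured gene it was 0.227, a value reached by 3 of 1000 shuffles. Some relation thus remains far from the ends of measured genes, though genes that were not measured may lie nearer. The difference of 0.176 between the 3' and the 5' side lies between the bounds set for the competing reading, so running-on and shared regulation of a region cannot be told apart here.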

How the results depend on the processing

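The fragment-weighted gene value, the use of all transcripts under a gene and the removal of transcripts under 200 bases were chosen only after the data were seen. Over all alternatives, planned and added, 410 values of group results stayed within 1.5 times and 33 moved. For list medians and for single genes and loci, this was judged on the fold behind the log2 value. A log2 value near 0 could therefore count as stayed and still take the other sign. The median of CDK inhibitors did so, at -0.39 in the main setting and 0.15 with a minimum of 5 FPKM. No list median past 2-fold took the other sign. With a pseudocount of 0.1 the lower counts were 2530 genes and 10221 isoforms, long noncoding RNA genes 163 higher and 266 lower, genes with opposite isoforms 2089 and the G2 and mitosis median -3.47. With a pseudocount of 5 higher and lower counts were 470 and 504 genes, 1171 and 908 isoforms, 12 and 16 long noncoding RNA genes and 483 and 469 unnamed loci, opposite isoforms numbered 69, and the medians were -1.43 for G2 and mitosis, -0.71 for DNA replication and -0.74 for homologous recombination and Fanconi genes. The changes in size follow from the construction, since a larger pseudocount shrinks every log2 ratio, and low values most. The balance of isoforms and of unnamed loci also turned with a pseudocount of 5. With a minimum of 5 FPKM, which leaves fewer members, higher and lower counts were 766 and 925 genes, 2327 and 1937 isoforms, 29 and 37 long noncoding RNA genes and 781 and 1008 unnamed loci, with 165 genes of opposite isoforms. The isoform balance turned there too, while that of unnamed loci did not. The excess of lower isoforms was thus not seen away from low FPKM. The histone median was then -1.29 and the cytokine median -1.71; the cause was not tested. With all transcripts under a gene 123 long noncoding RNA genes were higher and 205 lower; the cause was not tested. At 4-fold 103 genes had opposite isoforms, and at a q-value under 0.01 the authors' deposited table holds 909 transcripts, both through a stricter threshold.

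Of values for single genes and loci 2068 stayed and 155 moved, 75 with a pseudocount of 5 (all smaller in size), 52 with 0.1 (all larger), 21 with the highest isoform (6 larger, 15 smaller), 6 with all transcripts (3 larger, 3 smaller) and 1 with fragment weighting (larger, MALAT1 at 1.31). Of 190, 8 took the other sign under some setting, and 0 of these 8 were at least 2-fold in the main value. MALAT1 was among the 8 and passed 2-fold on the other side with fragment weighting. The percentile call of the fibroblast list held in 6 of 13 settings, that of the interferon list in 11. The telomere median kept its sign in 8 of 13 settings, and those of CDK inhibitors, immediate early, housekeeping and interferon genes in 12. Fragment weighting kept 2613 gene calls, lost 179, added 140 and turned 1. With status OK alone FN1, TPM2, CLIC4 and MGST3 gave no value. Counting noise alone called 255 of 16628 genes simulated without a difference, and 44 of 10303 at 5 FPKM or more. No paired analysis was possible because each group holds 1 library.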

Other observations

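The families and regions described here were chosen only after the result was seen. Metallothioneins, which bind zinc and copper, were higher in the senescent library in all 6 measured members, with a median log2 ratio of 2.75. MT2A was at 77.8 against 805 FPKM, MT1X at 6.57 against 62.5 FPKM, MT1G at 3.97 against 41.9 FPKM and MT1E at 21.2 against 51.7 FPKM. Pregnancy-specific glycoprotein genes were higher in all 9 measured members, with a median of 1.69. PSG4 was at 9.54 against 57.1 FPKM, PSG6 at 1.11 against 6.21 FPKM and PSG9 at 0.836 against 15.7 FPKM. The members of both families have similar sequences, so reads can be shared between them, and the 3 scalings tried only add to these ratios.

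Unnamed loci with gaps of at most 10000 bases formed 13 stretches of 20 or more loci. On chromosome 15, 57 of 57 loci from 70750484 to 70861279 and 35 of 35 from 70880594 to 70934824 were at least 2-fold higher in the senescent library. On chromosome 1, 35 of 35 loci from 232711742 to 232763629 were lower, beside SIPA1L2 with a log2 ratio of -3.31. On chromosome 6, 24 of 27 loci from 77798630 to 77859959 were lower, far from any measured gene. On chromosome 8, 23 of 25 loci from 118690692 to 118745967 were higher, 60762 bases from EXT1 with a log2 ratio of 0.97. On chromosome 3, 25 of 30 loci from 16008202 to 16099841 were lower, though the nearest measured gene, MIR563, had a log2 ratio of 1.32. Other stretches were not uniform: that with the most loci, on chromosome 12 from 24133786 to 24334347, held 12 lower and 0 higher of 65, that on chromosome 18 held 3 lower and 1 higher of 38, and that on chromosome 5 held 2 lower and 2 higher of 23.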
